A study of Mus musculus with 12 samples.

How the data were processed

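RNA was measured in soleus muscle of 24-month male C57BL/6N mice in 12 libraries, 3 in each of 4 groups: low functioning (LF) or high functioning (HF) by accelerating rotarod, each with laparotomy or control. Per the labels, the mice came from an aging colony, were housed singly with running wheels for 8 weeks, and soleus was taken 5 days after surgery. RNA was extracted with QIAzol and a column kit, and libraries were made after a polyA pull-down with a stranded Illumina kit, per the labels' protocols. The deposited values are gene-level TPM, and kallisto, DESeq2 and the GRCm38 build are named per the submitters' processing notes, without versions or roles. The strand setting of the quantification, read counts and any batch are not given in the sources used here. TPM sums ran from 956473 to 962830 per library over the 30323 genes of the table, so a few percent of the total lie outside it, and no counting interval or depth could be computed. Of the identifiers, 29857 matched a symbol in GENCODE M21 (GRCm38), which also gave coordinates, and 466 did not.

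From these values log2(TPM + 1) was computed. Genes with a mean of at least 1 TPM (10757) were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 mean per group, 8 residual degrees of freedom and two-sided tests. Adjusted p-values follow Benjamini and Hochberg over the genes of each of 7 contrasts, with a threshold of 0.05. The contrasts were laparotomy against control in LF, in HF and averaged, their interaction, and HF against LF in controls, after laparotomy and averaged. Gene lists (36 fixed, 34 with at least 5 tested members; the neutrophil and lymphocyte lists had 2 each and were not tested) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Medians of lists and log2 differences of genes are printed minus the median of all tested genes in that contrast. Slow myosin is Myh7 as a percent of Myh7, Myh2, Myh1 and Myh4 TPM. The mitochondrially encoded share is the percent of TPM in 13 genes. Both were compared by exact permutation tests, two-sided, with labels permuted within LF and within HF for averaged values, and the HF against LF comparison of both shares and of PC1 was chosen after the data were seen.

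Groups, contrasts, tests, lists, the naming rule and most of the alternatives were fixed before the data were examined. The rule named up to 10 higher and 10 lower genes past the threshold by smallest p, leaving out predicted and Riken symbols and genes whose groups overlapped, in the LF, HF and averaged laparotomy contrasts and the averaged HF against LF contrast. Where fewer than 5 passed, it was filled to 5, again only with genes whose groups did not overlap. It also named 3 members of each list past camera, 14 genes for laparotomy and the 5 smallest p of the interaction. To save room the text gives 3 members only for lists that held without each library, 1 for the others, and few for HF against LF within a treatment and for the 10 interaction lists that did not hold. A few genes that the rule names are not reported here. Alternatives were pseudocounts of 0.5 and 0.1, no filter, a mean of at least 5 TPM, median-of-ratios size factors, quantile normalization, TPM rescaled without the 13 mitochondrially encoded and the 10 highest genes, robust eBayes, array weights, a threshold of 0.10, a fit of only the groups compared, a fast muscle covariate (log2 of Myh4 + 1 minus log2 of Myh7 + 1) and leaving out each library. Added after seeing the data were removal of a length and GC trend, leaving out the 3 libraries with Myh4 above 30 TPM, permutation of list means and the mitochondrially encoded share with its chromosome 1 copies.

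Near-identical copies were searched in the transcripts at 95% identity and 80% cover. Of 211 named genes, 32 overlap exons of another tested gene, 7 of them on the same strand (Manf, Sap25, Snurf, mt-Atp6, mt-Atp8, mt-Co3 and mt-Nd4l). Those overlapped on the opposite strand include Alas2, Cebpb, Cnp, Entpd4, Myh7b, Ndufb2, Pfkm, Prg4, Proser3, Psmb9, Psmc3ip, Rfc5, Rpl15, Rpl35, Rps28, Tap1 and Tnnc2, and the values of all these genes are uncertain. The steps were tested in 5 simulations per contrast with 200 of 10757 genes changed. Of calls, 4.91% were false in LF, 5.56% in HF, 4.78% in averaged laparotomy and 3.85% in averaged HF against LF. The last recovered 73.7% of changes of 0.5 log2 and 97% of 1 log2. A list shifted by 0.3 log2 passed in 3 of 5 for LF laparotomy (first in 4, adjusted p up to 0.259). It passed in 5 each for HF, averaged laparotomy and averaged HF against LF, and 2 other lists passed over all 20. These rates may not hold for real lists: 0 passed with an estimated correlation.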

Results

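RNA was sequenced from the soleus, a postural muscle of the hind limb, of male C57BL/6N mice aged 24 months that had been kept with running wheels for 8 weeks. Low functioning (LF) and high functioning (HF) mice, sorted by their performance on an accelerating rotarod, had either a laparotomy or a control treatment, and muscle was collected 5 days later. The 12 libraries form 4 groups of 3, named here LF control, LF laparotomy, HF control and HF laparotomy with a replicate number that pairs nothing. The labels do not say that each library comes from a separate mouse, so every p-value here measures only the spread between these libraries, which may be technical. The values are transcript abundances scaled to a fixed library total (TPM), so the depth is unknown. Each library listed 16993 to 18148 genes above 0 and 10324 to 10954 at 1 TPM or more. The 13 mitochondrially encoded genes held 26.4% to 39.7% of all TPM, or 35.5% to 48.1% with their chromosome 1 copies. The 10 most abundant genes, which may include these, held 31.4% to 40.1%. Of 30323 genes, 10757 with a mean of at least 1 TPM were tested with limma.

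On the first principal component of log2(TPM + 1) every HF library lay above every LF library of the same treatment, while LF laparotomy 1 (1.86) lay above HF control 2 (1.19). This component took 48.1% of the variance, and its score was 34.5 higher in HF than in LF (exact permutation within treatments, two-sided p = 0.005, the smallest possible). The group means were -19.3 in LF control, -15.1 in LF laparotomy, 11.1 in HF control and 23.4 in HF laparotomy. Within function the laparotomy difference in this score was 8.21 (exact permutation p = 0.18).

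**Figure D1:**
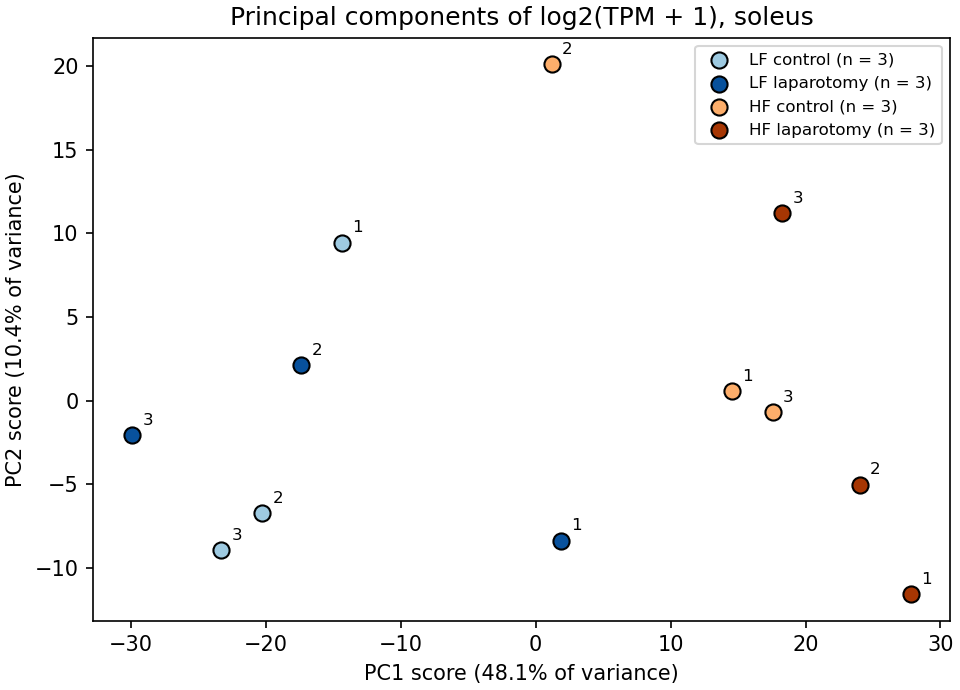
Scores of the 12 libraries on PC1 and PC2 of log2(TPM + 1), with the share of variance on each axis and 1 point per library, labelled by replicate. The LF control libraries lie between -23.3 and -14.3 on PC1 and the HF laparotomy libraries between 18.2 and 27.8, while LF laparotomy 1 (1.86) and HF control 2 (1.19) lie near each other.

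The first question was how HF and LF soleus differ, averaged over the treatments, with 6 libraries on each side. Log2 differences are given ± their standard error, relative to the median of all tested genes, because TPM scaling moved that median: it was -0.15 as deposited, 0.013 with median-of-ratios size factors (size factors below) and -0.089 on TPM rescaled without the most abundant genes. The adjusted p-values test the differences as deposited, before this centring. Lars2, the mitochondrial leucyl-tRNA synthetase, was lower in HF (-1.01 ± 0.10, adjusted p = 8.8e-05). Its mean ± SD was 15.6 ± 1.05 TPM in LF control, 18 ± 3.53 in LF laparotomy, 8.72 ± 1.26 in HF control and 5.48 ± 0.447 in HF laparotomy (n = 3 each). Dlst, a core subunit of the 2-oxoglutarate dehydrogenase complex of the citric acid cycle, fell (-1.23 ± 0.13, adjusted p = 0.000147). So did Acsl1, which activates long-chain fatty acids (-0.70 ± 0.083, adjusted p = 0.000147), and Slc41a1, a magnesium transporter (-0.68 ± 0.086, adjusted p = 0.000197). Lower too were Efr3b (-0.96 ± 0.11), Fam129a (-0.89 ± 0.10), Pitpnc1 (-0.72 ± 0.085), Man2a2 (-1.14 ± 0.13), a Golgi mannosidase, Sbk3 (-0.74 ± 0.09) and Entpd4 (-0.98 ± 0.099), the last uncertain because reads can be shared with its near-identical copy Entpd4b. Their adjusted p lay between 8.8e-05 and 0.000176. Higher in HF were Ntan1, an amidase that acts on N-terminal asparagine (0.87 ± 0.073, adjusted p = 0.000176), Xpo6, a nuclear export receptor for actin with profilin (0.88 ± 0.091, adjusted p = 0.000354), and Egfl7, which endothelial cells secrete (0.77 ± 0.073, adjusted p = 0.00031). The other leading genes were Myl10 (0.65 ± 0.069), Atf7 (0.60 ± 0.062) and the ribosomal protein genes Rpl28 (0.78 ± 0.082), Rps20 (0.70 ± 0.066), Rps16 (0.65 ± 0.069), Rps29 (0.61 ± 0.061) and Rpl38 (0.58 ± 0.057). These 20 genes were taken only from those whose HF and LF libraries did not overlap in either treatment, and none lost its call when any 1 of the 12 libraries was left out.

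In GRCm38 (GENCODE M21) these lead genes lie as follows: Ntan1 (ENSMUSG00000022681) on chromosome 16 from 13818845 to 13835451, Egfl7 (ENSMUSG00000026921) on chromosome 2 from 26580014 to 26593120, Lars2 (ENSMUSG00000035202) on chromosome 9 from 123366927 to 123462666, Dlst (ENSMUSG00000004789) on chromosome 12 from 85110833 to 85134845 and Acsl1 (ENSMUSG00000018796) on chromosome 8 from 46471037 to 46536051. Exons of Ntan1, Egfl7, Rpl28 and Man2a2 overlap those of a gene on the opposite strand (Pdxdc1, Agpat2, Ube2s and Hddc3), and the strand setting of the quantification is not given in the sources used here, so their values are uncertain to that extent. In all, limma called 4447 of 10757 genes, 649 higher and 3798 lower in HF (14.6% higher). The split moved with the scaling: on TPM rescaled without the 13 mitochondrially encoded and the 10 highest genes 1104 were higher and 3312 lower (25% higher). With size factors 2146 were higher and 2211 lower (49.3% higher), with quantile normalization 46.0% were higher and with the length and GC trend removed 44.4%, all of which centre the genes. Without single libraries the count lay between 3627 and 5100.

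Cytosolic ribosomal protein genes rose together in HF: of 77 tested, 50 rose and 1 fell over all genes (54 and 1 adjusted over the list alone, 71 and 0 with size factors), with a median of 0.41 (camera adjusted p = 1.28e-32, 0.428 with an estimated correlation). Its median before centring was 0.26 as deposited, 0.33 on rescaled TPM, 0.29 with quantile normalization and 0.46 with size factors. Over all genes this HF against LF difference had a Spearman correlation of -0.244 with transcript length and 0.226 with GC content, its median before centring going from -0.0667 in the shortest quartile to -0.241 in the longest. RNA or library quality could bring this; with the trend removed the ribosomal list stood at 0.33 (camera adjusted p = 2.62e-23). Among nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 26 rose and 7 fell over all genes (26 and 7 over the list alone, 53 and 4 with size factors), of 75 tested (median 0.30, camera adjusted p = 4.64e-11, 0.931 with an estimated correlation). The first were Ndufb2 (0.48 ± 0.069), Atp5b (0.47 ± 0.071) and Ndufa13 (0.52 ± 0.085). Of 18 endothelial markers, 8 rose and 0 fell over all genes (8 and 0 over the list alone, 10 and 0 with size factors), with a median of 0.41 (camera adjusted p = 2.7e-09, 0.931 with an estimated correlation). After Egfl7 the first were Sox18 (0.67 ± 0.12), a vascular transcription factor, and Ly6c1 (0.70 ± 0.11), which has the near-identical copy Ly6c2. Schwann and nerve markers stood 0.64 above the other genes (camera adjusted p = 1.75e-05, 0.931 with an estimated correlation): 3 rose and 0 fell over all genes (5 and 0 over the list alone, 7 and 0 with size factors), of 9 tested. Prx, a myelin protein gene, rose by 0.86 ± 0.20 (adjusted p = 0.0124, 0.057 without a filter on low values). Without HF laparotomy 3 the list stood at 0.424, its mean being 3.97 in that library and between 2.44 and 2.93 in the other libraries. The interferon response list stood 0.50 higher (camera adjusted p = 2.4e-08, 0.931 with an estimated correlation). Of its 27 tested members, 3 rose and 0 fell over all genes (0 and 0 over the list alone, 9 and 0 with size factors). The 13 mitochondrially encoded genes had a median of 0.24 (camera adjusted p = 0.00213, 0.931 with an estimated correlation). First were mt-Co3 (0.34 ± 0.097, near-identical copy Gm28437), mt-Cytb (0.30 ± 0.077) and mt-Nd1 (0.29 ± 0.092), none passing. This list call ended with quantile normalization (adjusted p = 0.523) and with the length and GC trend removed (0.143), range 0.00155 to 0.523. Its median was 0.148 without LF laparotomy 3.

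Genes of mitochondrial biogenesis and dynamics fell in HF: 1 rose and 13 fell over all genes (1 and 13 over the list alone, 1 and 9 with size factors), of 19 tested (median -0.21, camera adjusted p = 0.0153, 0.931 with an estimated correlation). They include Ppargc1a (-0.76 ± 0.13, adjusted p = 0.000514), the coactivator that drives mitochondrial gene expression, Opa1 (-0.80 ± 0.12, adjusted p = 0.000379), which fuses inner mitochondrial membranes, and Prkaa2 (-0.71 ± 0.12, adjusted p = 0.000446), a catalytic subunit of AMP-activated kinase. Of 28 genes of fatty acid uptake and oxidation, 0 rose and 18 fell over all genes (1 and 20 over the list alone, 1 and 9 with size factors), with a median of -0.26 (camera adjusted p = 0.0116, 0.931 with an estimated correlation). After Acsl1 the first were Etfdh (-0.42 ± 0.096) and Slc25a20 (-0.31 ± 0.082), the carnitine carrier of mitochondria. Glycolysis and glycogen genes were lower as well: 2 rose and 16 fell over all genes (2 and 17 over the list alone, 3 and 13 with size factors), of 23 tested (median -0.32, camera adjusted p = 0.0211, 0.931 with an estimated correlation). They included Ppp1r3a (-0.67 ± 0.11) and Pfkm (-0.42 ± 0.077). The glycolysis call ended without HF control 2 (adjusted p = 0.0576) and without HF laparotomy 3 (adjusted p = 0.0665). A minimum of 5 TPM ended it too (adjusted p = 0.0533) and ended the biogenesis call (adjusted p = 0.075, range over the alternatives 0.00445 to 0.075). The fatty acid call ended without the 3 libraries with Myh4 above 30 TPM (adjusted p = 0.0711, range 0.000113 to 0.0711). By fry, which tests whether members move one way on balance, 3 lists passed: ribosomal (adjusted p = 0.00262), biogenesis and glycolysis (0.0188 each). Exact permutation of list means was chosen after the data were seen. It passed 5 at adjusted p = 0.034: ribosomal, Schwann and nerve, fatty acid, biogenesis and glycolysis. Both tests are before centring, so the lower lists include the all-gene shift of -0.15.

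**Figure D2:**
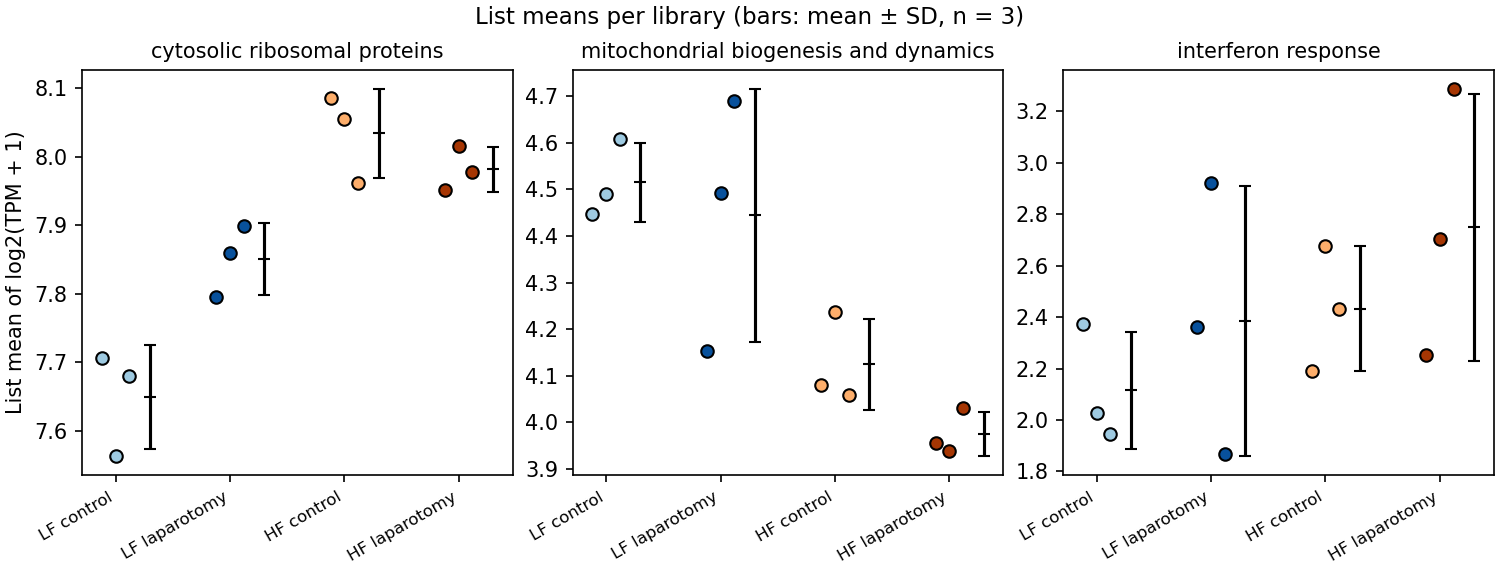
Mean log2(TPM + 1) of the cytosolic ribosomal protein, mitochondrial biogenesis and interferon response lists in each library, with bars for the mean and SD of 3 libraries. Ribosomal list means lie between 7.56 and 7.90 in the LF libraries and between 7.95 and 8.09 in the HF libraries.

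Another 7 lists passed camera with higher values in HF, but each lost its call without at least 1 library and with an estimated correlation (adjusted p = 0.931, or 0.954 for extracellular matrix). They were tendon (median 0.31, adjusted p = 0.0211, first member Angptl7 at 0.58 ± 0.20), slow fibre contractile (0.21, 0.0239, first member Myh7b at 0.79 ± 0.12), immediate early genes (0.15, 0.0281, first member Ier2 at 0.48 ± 0.09) and acute phase (0.38, 0.0308, first member Nfkbia at 0.47 ± 0.089). The others were macrophage (0.22, 0.0308, first member Tyrobp at 0.66 ± 0.33), fibroadipogenic (0.19, 0.0308, first member Ly6a at 0.65 ± 0.16) and extracellular matrix (0.075, 0.0239, first member Lama4 at 0.68 ± 0.11). Ly6a passed alone (adjusted p = 0.0227), but not without LF control 3 (adjusted p = 0.0582), LF laparotomy 3 (0.0548), HF laparotomy 2 (0.0584) or HF laparotomy 3 (0.0538), nor without a filter on low values (0.0858) or without the 3 Myh4 libraries (0.142). Without LF control 3 the adjusted p was 0.0525 for acute phase, 0.436 for extracellular matrix, 0.206 for macrophage, 0.296 for fibroadipogenic and 0.165 for tendon. Without LF laparotomy 3 the adjusted p was 0.109 for slow fibre contractile, 0.109 for acute phase, 0.158 for extracellular matrix, 0.188 for macrophage, 0.175 for fibroadipogenic and 0.109 for tendon. Without HF control 2 the adjusted p was 0.0872 for extracellular matrix, 0.12 for macrophage and 0.0702 for fibroadipogenic. For acute phase it was 0.0589 without HF control 3 and 0.0526 without HF laparotomy 2, the last also giving 0.0591 for immediate early genes. Without HF laparotomy 3 the adjusted p was 0.0773 for acute phase, 0.194 for extracellular matrix, 0.346 for macrophage, 0.216 for fibroadipogenic and 0.0659 for immediate early genes. Size factors ended all 7 calls. Of 7 settings they held in 3 for tendon (adjusted p up to 0.243), 4 for slow fibre (0.524), 2 for immediate early genes (0.145), 2 of 6 for acute phase (0.273), 1 for macrophage (0.519), 3 for fibroadipogenic (0.192) and 2 for extracellular matrix (0.243). For extracellular matrix genes the median (-0.073) and mean (-0.040) before centring were below 0, against the upward camera call. Among slow fibre genes Myh7b (adjusted p = 0.0021) and Tnnc1 (0.50 ± 0.093, adjusted p = 0.0103), a troponin of slow muscle, rose. Myosins and atrophy genes were chosen here after their values were seen: Myh2 (-0.80 ± 0.12, adjusted p = 0.000374), the type 2A heavy chain, fell, while Myh1 (-0.30 ± 0.24), Myh4 (-0.38 ± 0.79) and the slow Myh7 (-0.04 ± 0.11) did not pass. Fbxo32 and Trim63, ubiquitin ligases induced in muscle atrophy, stood at -0.31 ± 0.11 (adjusted p = 0.00682, 0.203 with the length and GC trend removed) and -0.26 ± 0.14 (adjusted p = 0.0363). Trim63 kept its call only when the library left out was LF control 1, LF laparotomy 2, HF control 2 or HF laparotomy 3, with adjusted p up to 0.0887 without the others. Its call also ended with size factors (adjusted p = 0.217), quantile normalization (0.143), rescaled TPM (0.0533), array weights (0.102), the length and GC trend removed (0.18), no filter on low values (0.117) and without the 3 Myh4 libraries (0.154).

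Of the interferon genes, Xaf1 (0.67 ± 0.19, adjusted p = 0.0456), Psmb8 (0.71 ± 0.21, adjusted p = 0.0459) and Bst2 (0.85 ± 0.27, adjusted p = 0.0494) passed with all libraries. Xaf1 stayed past the threshold only without LF laparotomy 2, HF control 1 or HF laparotomy 1 (adjusted p up to 0.104 otherwise). Psmb8 did so only without LF control 1, LF laparotomy 2, HF laparotomy 1 or HF laparotomy 2 (up to 0.106 otherwise). Bst2 did so only without LF control 1, LF laparotomy 2, HF control 1 or HF laparotomy 1 (up to 0.116 otherwise). No filter on low values, robust eBayes, array weights, the fast muscle covariate and leaving out the 3 Myh4 libraries each ended all 3 calls (adjusted p from 0.0564 to 0.378). That of Bst2 ended also on rescaled TPM (0.0513) and with the length and GC trend removed (0.068). Other lists did not pass: adipocyte (median 0.48, adjusted p = 0.0613), erythroid (0.39, 0.174), glucocorticoid response (0.11, 0.184), heat shock (-0.094, 0.283), autophagy (-0.046, 0.409) and fast fibre contractile (-0.12, 0.481). Nor did circadian clock (-0.13, 0.569), unfolded protein (0.011, 0.725) and satellite cell (-0.020, 0.823). Slow myosin (Myh7) made up 46.1% ± 2.22 of the 4 adult myosin heavy chains in LF control, 43.1% ± 4.88 in LF laparotomy, 57.7% ± 10.9 in HF control and 52.9% ± 6.03 in HF laparotomy (mean ± SD, n = 3). It was 10.7 points higher in HF (exact permutation p = 0.03), a test chosen after the data were seen. It did not hold without LF control 1 (exact p = 0.05), LF control 2 (0.065), LF control 3 (0.05), LF laparotomy 1 (0.065), LF laparotomy 3 (0.06), HF laparotomy 1 (0.055) or HF laparotomy 3 (0.055).

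Asked within the treatments, 3 libraries against 3, the HF and LF control muscles differed. In controls Rpl28 (0.98 ± 0.12, adjusted p = 0.00873) and Egfl7 (0.82 ± 0.10, adjusted p = 0.0101) rose, and Ppp1r3a (-0.73 ± 0.15, adjusted p = 0.0155), a glycogen-targeting phosphatase subunit, and Ppargc1a (-0.84 ± 0.18, adjusted p = 0.0161) fell. All 15 named genes past the threshold in controls lost their call without 1 library or more. For these 4 it was LF control 2 (adjusted p = 0.0506, 0.054, 0.077 and 0.077), and for Ppp1r3a and Ppargc1a also LF control 3 (0.0615 and 0.0615), HF control 1 (0.0594 and 0.0661) and HF control 3 (0.0619 and 0.0592). Without a filter on low values these 2 had adjusted p = 0.0568 and 0.0611. Ribosomal protein genes rose in controls: of 77, 46 rose and 0 fell over all genes (68 and 0 over the list alone, 70 and 0 with size factors), with a median of 0.51 (adjusted p = 2.07e-42, 0.219 with an estimated correlation). Oxidative phosphorylation genes were higher (median 0.31, adjusted p = 3.52e-12, 0.989 with an estimated correlation): of 75, 10 rose and 3 fell over all genes (19 and 4 over the list alone, 24 and 2 with size factors). So were endothelial (median 0.41, adjusted p = 7.81e-08), interferon (0.36, adjusted p = 4.01e-05), Schwann and nerve (0.46, adjusted p = 0.00613) and slow fibre genes (0.37, adjusted p = 0.0081), all with adjusted p = 0.989 with an estimated correlation. Mitochondrial biogenesis genes were lower: 0 rose and 6 fell over all genes (1 and 9 over the list alone, 1 and 6 with size factors), of 19 (median -0.20, adjusted p = 0.0148, 0.989 with an estimated correlation). Glycolysis (median -0.27, adjusted p = 0.00729), tendon (0.34, adjusted p = 0.0219) and immediate early genes (0.16, adjusted p = 0.0219) passed too, but not without each library or with an estimated correlation (adjusted p = 0.989). With LF control 3 left out it was 0.665 for tendon. With HF control 2 left out it was 0.0755 for glycolysis and 0.0724 for tendon. With HF control 3 left out it was 0.0672 for immediate early genes. Of 7 other settings the tendon call held in 2 (adjusted p up to 0.568), slow fibre in 5 (0.481), immediate early genes in 5 (0.089), mitochondrial biogenesis in 6 (0.089) and Schwann and nerve in 5 of 6 (0.0662). Limma called 1127 genes in controls, 262 higher and 865 lower (23.2% higher), against 447 and 1704 on rescaled TPM (20.8% higher). With the centring scalings 974 were higher and 960 lower (size factors, 50.4% higher) and 45.3% were higher (quantile normalization), the all-gene median being -0.11 as deposited. This count hung on single libraries: it was 2 without LF control 2 (the pseudogenes Gm8325 and Gm5537), 47 without HF control 1, 48 without LF control 3 and 66 without HF control 3. It was 579 without HF laparotomy 2, 735 without LF control 1, 2054 without LF laparotomy 3 and 2080 without LF laparotomy 1.

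After laparotomy, Acsl1 (-0.80 ± 0.12, adjusted p = 0.00195), Opa1 (-0.87 ± 0.18, adjusted p = 0.00403) and Pfkm (-0.44 ± 0.11, adjusted p = 0.00438), the muscle phosphofructokinase, were lower in HF. Higher were Ddit4 (0.999 ± 0.18, adjusted p = 0.0104), a stress-induced brake on mTOR, Lama4 (0.998 ± 0.16, adjusted p = 0.00669), a basement membrane laminin, and Rps20 (0.64 ± 0.093, adjusted p = 0.00837). Without the 3 Myh4 libraries, Ddit4 (adjusted p = 0.0671) and Rps20 (0.0507) lost their calls. Fatty acid genes fell: of 28, 0 rose and 17 fell over all genes (0 and 21 over the list alone, 0 and 5 with size factors), with a median of -0.36 (adjusted p = 0.000941, 0.776 with an estimated correlation). Schwann and nerve markers (0.81, adjusted p = 2.53e-07), interferon genes (0.58, adjusted p = 1.92e-09), endothelial markers (0.41, adjusted p = 1.15e-08) and ribosomal genes (0.29, adjusted p = 7.04e-17) were higher relative to other genes by camera, each with adjusted p = 0.776 with an estimated correlation. So were, with the same adjusted p = 0.776, the mitochondrially encoded (0.43, adjusted p = 3.48e-07) and acute phase lists (0.53, adjusted p = 0.00295). Quantile normalization ended these last calls (adjusted p = 0.225, range 4.83e-09 to 0.225, and 0.073, range 0.00217 to 0.103), and size factors ended that of the acute phase list (0.103). Oxidative phosphorylation stood 0.27 above other genes (adjusted p = 1.49e-07, 0.776 with an estimated correlation). Its member calls turned with the scaling: 1 rose and 6 fell over all genes (0 and 6 over the list alone, 22 and 2 with size factors). These 8 calls held without each library, but without LF laparotomy 3 the medians were -0.203 (fatty acid), 0.203 (interferon) and 0.211 (mitochondrially encoded). Without HF laparotomy 3 they were 0.369 (Schwann and nerve) and 0.296 (interferon), without HF laparotomy 2 0.313 (acute phase) and without HF laparotomy 1 0.165 (oxidative phosphorylation). Another 9 lists passed camera, but not with an estimated correlation (adjusted p = 0.776, or 0.806 for glycolysis): mitochondrial biogenesis (median -0.24, adjusted p = 0.015, first member Opa1 at -0.87 ± 0.18), glycolysis (-0.32, 0.0441, first member Pfkm at -0.44 ± 0.11), extracellular matrix (0.18, 0.000752, first member Lama4 at 0.998 ± 0.16) and fibroadipogenic (0.29, 0.00141, first member Ly6a at 0.84 ± 0.22). The others were macrophage (0.32, 0.00326, first member Mrc1 at 0.41 ± 0.23), erythroid (0.67, 0.0146, first member Hbb-bs at 0.87 ± 0.49), adipocyte (0.59, 0.037, first member Fabp4 at 0.58 ± 0.15), glucocorticoid response (0.11, 0.037, first member Ddit4 at 0.999 ± 0.18) and tendon (0.21, 0.0404, first member Prg4 at 0.60 ± 0.30). Ly6a passed alone (adjusted p = 0.0491), but only LF laparotomy 2 or HF laparotomy 1 could be left out without ending its call (adjusted p up to 0.194, without LF laparotomy 3). It also ended with no filter on low values (0.153), rescaled TPM (0.0501), robust eBayes (0.061), only the groups compared (0.0932), the fast muscle covariate (0.0646) and without the 3 Myh4 libraries (0.181). Leaving out LF laparotomy 1 made the adjusted p 0.0822 for glucocorticoid response and 0.0665 for glycolysis. Leaving out LF laparotomy 2 made it 0.0624 for adipocyte. Leaving out LF laparotomy 3 made it 0.0807 for glycolysis, 0.0807 for extracellular matrix, 0.141 for macrophage, 0.0807 for adipocyte, 0.205 for erythroid, 0.0807 for fibroadipogenic and 0.357 for tendon. Leaving out HF control 2 made it 0.0551 for glycolysis. Leaving out HF laparotomy 1 made it 0.0649 for tendon. Leaving out HF laparotomy 2 made it 0.108 for glucocorticoid response and 0.0914 for adipocyte. Leaving out HF laparotomy 3 made it 0.107 for glucocorticoid response, 0.0556 for mitochondrial biogenesis, 0.258 for glycolysis, 0.0902 for extracellular matrix, 0.262 for macrophage, 0.254 for adipocyte, 0.11 for erythroid, 0.107 for fibroadipogenic and 0.0902 for tendon. Of 7 settings the calls held in 1 for adipocyte (adjusted p up to 0.504), 4 for erythroid (0.314), 5 for extracellular matrix (0.0875), 3 for glucocorticoid response (0.238), 4 for glycolysis (0.129), 4 for macrophage (0.3), 3 for tendon (0.364) and 6 for mitochondrial biogenesis (0.0673). Size factors ended the first 7 of these. Before centring, the medians of the glucocorticoid (-0.080) and extracellular matrix lists (-0.018) were below 0, against their upward calls. After laparotomy limma called 2796 genes, 161 higher and 2635 lower (5.76% higher), against 435 and 1364 on rescaled TPM (24.2% higher) and 1001 and 1154 with size factors (46.5% higher). With quantile normalization 43.4% were higher, and the all-gene median was -0.19 as deposited. The count was 1048 without LF laparotomy 2, 1078 without HF laparotomy 2, 1105 without HF laparotomy 1 and 1144 without LF laparotomy 3. Both treatments shared 66 higher (3.92 if independent) and 803 lower calls (212), 0 in opposite directions. These contrasts share each gene's residual variance, so they are not independent. HF and LF libraries did not overlap for 40.4% of genes in controls and 40.5% after laparotomy (chance 10%).

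**Figure D3:**
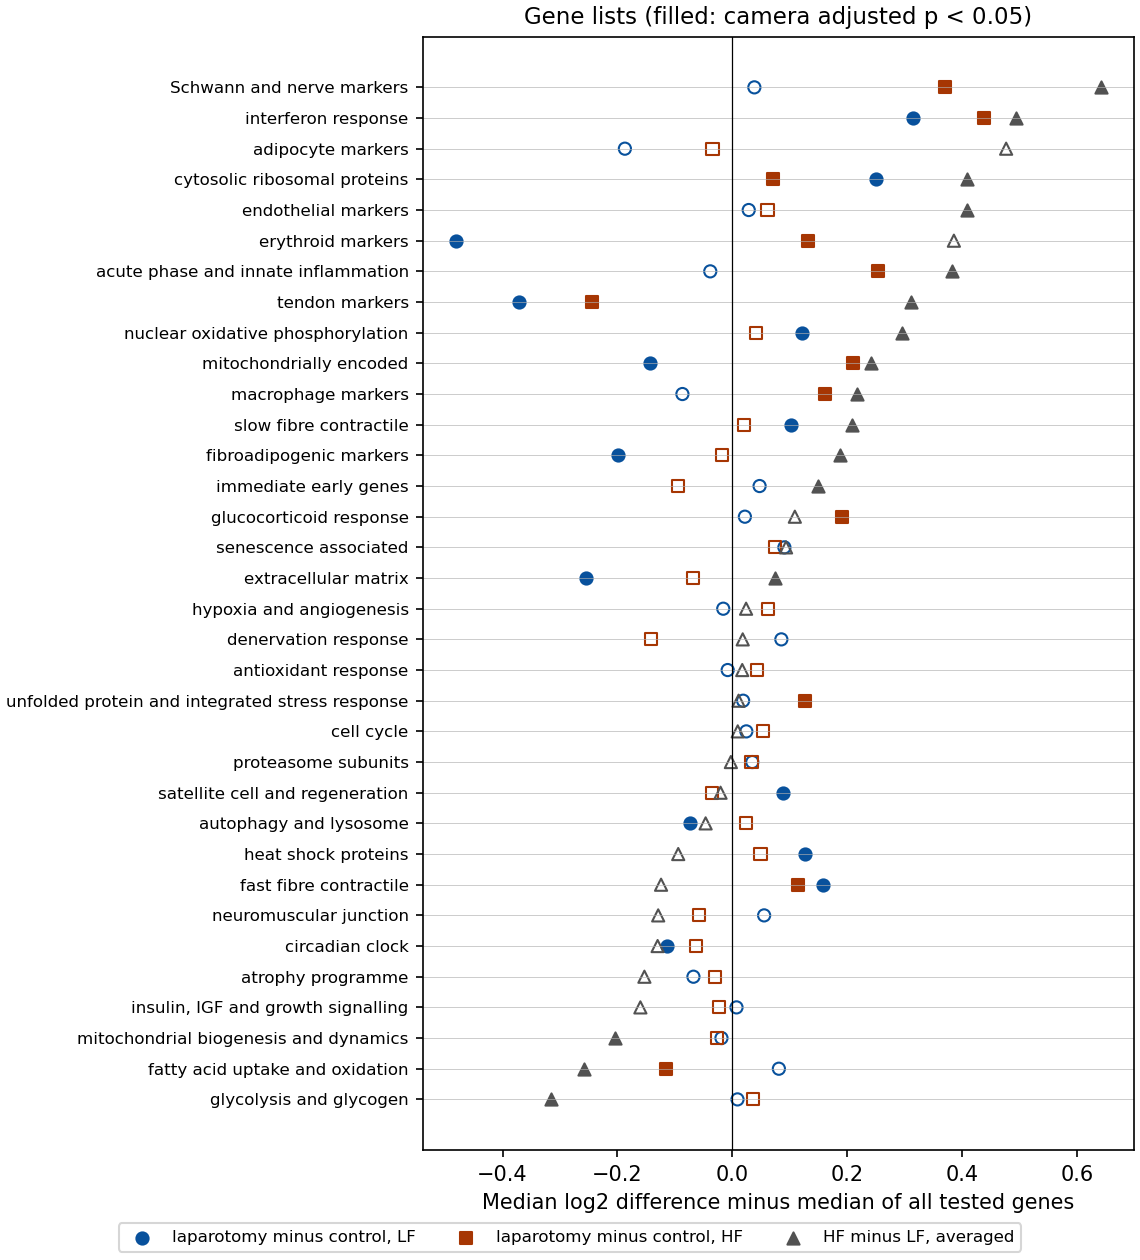
Median log2 difference of each of the 34 tested gene lists minus the median of all tested genes, for laparotomy minus control in LF (circles) and HF (squares) and HF minus LF averaged (triangles), filled where the camera call with preset correlation passed. The widest upward shifts are HF minus LF for Schwann and nerve markers (0.64) and interferon response (0.50), and 0 lists pass with an estimated correlation.

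Some of the single-gene differences between HF and LF were in pseudogenes, which were singled out after their values were seen. All 11 genes past the threshold with a fitted change of at least 4-fold before centring (pseudocount 1) were lower in HF. Relative to all genes 10 were 4-fold lower and 0 higher, with Gm14117 at -1.87. All 11 are annotated pseudogenes with a near-identical copy elsewhere (95.7% to 100% identity), so their values are uncertain. Of them, 2 (Gm10359 and Gm12671) hold identical values in every library. Gm8325 on chromosome 3 (60877014 to 60877587, GRCm38, copy Gm20431) had means of 47.8 and 37.4 TPM in LF control and LF laparotomy, and 0 and 0.0513 TPM in HF control and HF laparotomy. Gm5537, a copy of the glycolytic gene Pgk1, had 23.5 and 27.2 TPM in LF and was listed at 0 in every HF library, and Gm10171, a copy of the mitochondrial import gene Timm23, had 6.90 and 11.9 TPM in LF and 0 in HF. The 7 parent genes that were tested had a median log2 difference of -0.026, from -0.27 to 0.26, with standard errors up to 0.105.

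**Figure D4:**
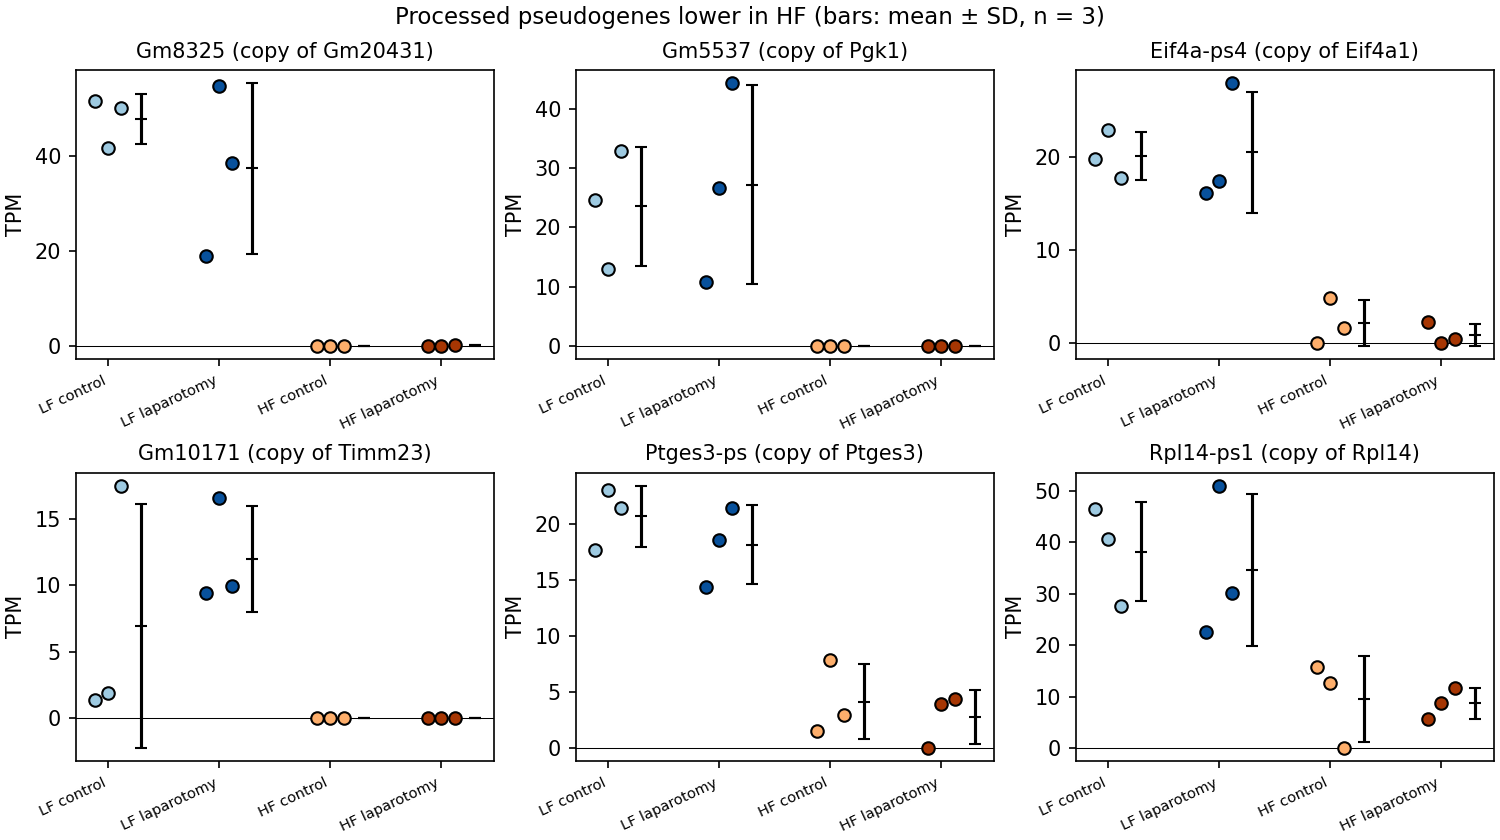
TPM of 6 pseudogenes in each library, with bars for the mean and SD of 3 libraries per group, and the near-identical parent gene named above each panel. Gm8325 and Gm5537 lie at 10.8 TPM or more in every LF library and at 0.154 TPM or less in every HF library.

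The second question was what laparotomy changes in LF soleus, 3 libraries against 3. The gene with the smallest p was Tnfrsf12a, the receptor for TWEAK, at 25.1 ± 3.81 TPM in control and 53.8 ± 3.1 after laparotomy (1.11 ± 0.20, adjusted p = 0.914). Next were Nmrk2, a muscle nicotinamide riboside kinase (0.86 ± 0.16, adjusted p = 0.914), Lmcd1 (0.47 ± 0.089), Arhgap29 (0.55 ± 0.12) and the pseudogene Rps12-ps3 (0.67 ± 0.15), which has the near-identical copy Rps12. On the lower side stood Med31 (-0.39 ± 0.10), Pik3cd (-0.40 ± 0.11), Rwdd3 (-0.40 ± 0.12), Mfsd1 (-0.34 ± 0.10) and Mbip (-0.35 ± 0.11), and none of these 10 genes passed. Limma called 0 of 10757 genes (291 at an unadjusted p under 0.05, 156 of them higher), and robust eBayes called 0. Limma with array weights called 2 (Nmrk2, adjusted p = 0.0484, and Gm10401, adjusted p = 0.0484). Without LF control 3 the count was 1 (Gm10171, adjusted p = 0.000637), and without LF laparotomy 3 it was 1 (Gm10197, adjusted p = 0.0375). In simulated data with 200 of 10757 genes changed, this comparison recovered 38.2% of changes of 0.5 log2 and 90.4% of changes of 1 log2. LF control and laparotomy libraries did not overlap for 6.46% of genes, where chance gives 10%.

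As a group, ribosomal protein genes stood above other genes by camera after laparotomy in LF (median 0.25 over 77, camera adjusted p = 2.14e-50, 0.136 with an estimated correlation). By limma 0 passed over all genes and 19 were higher over the list alone, led by Rps21 (0.47 ± 0.11), Rps15 (0.41 ± 0.10) and Rps4l (0.66 ± 0.17). Oxidative phosphorylation genes (0.12, camera adjusted p = 5.13e-07, 0.845 with an estimated correlation) and heat shock proteins (0.13, camera adjusted p = 0.000249, 0.845 with an estimated correlation) were higher too. The heat shock list was led by the chaperone genes Hspb3 (0.34 ± 0.092), Hspb1 (0.50 ± 0.14) and Hspa1a (0.60 ± 0.21). The first members for oxidative phosphorylation were Ndufs7 (0.36 ± 0.15), Ndufb7 (0.31 ± 0.14) and Cox6a2 (0.26 ± 0.13), and this call ended with quantile normalization (adjusted p = 0.986, range 1.08e-06 to 0.986). These 3 of 14 lists held without each of the 12 libraries, though the heat shock median was 0.0539 without LF control 1, 0.0543 without LF laparotomy 2 and 0.0749 without LF laparotomy 3. That of oxidative phosphorylation was 0.081 without LF control 2 and 0.0778 without LF laparotomy 1. No member of any list passed over all genes.

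The remaining lists held neither without each library nor with an estimated correlation (adjusted p = 0.845, or 0.967 for autophagy). Upward were interferon response (median 0.31, adjusted p = 2.49e-06, first member Psmb9 at 0.60 ± 0.27), fast fibre contractile (0.16, 0.0124, first member Tnnc2 at 0.35 ± 0.17), slow fibre contractile (0.10, 0.0254, first member Csrp3 at 0.73 ± 0.23) and satellite cell (0.089, 0.0272, first member Myh8 at 0.46 ± 0.16). Downward were extracellular matrix (median -0.26, adjusted p = 1.82e-05, first member Col15a1 at -0.32 ± 0.14), mitochondrially encoded (-0.14, 0.00115, first member mt-Co2 at -0.84 ± 0.30), fibroadipogenic (-0.20, 0.00319, first member Col15a1 at -0.32 ± 0.14) and autophagy and lysosome (-0.073, 0.00947, first member Ctsl at -0.27 ± 0.13). So were circadian clock (-0.11, 0.00947, first member Per2 at -0.30 ± 0.15), tendon (-0.37, 0.00947, first member Chad at -0.57 ± 0.29) and erythroid (-0.48, 0.0178, first member Hba-a2 at -0.75 ± 0.48), and mt-Co2 and Hba-a2 have near-identical copies. If LF control 1 was left out, the adjusted p was 0.316 for fast fibre contractile, 0.621 for extracellular matrix (turned), 0.063 for satellite cell, 0.586 for erythroid, 0.959 for fibroadipogenic and 0.621 for tendon (turned). If LF control 2 was left out, it was 0.453 for slow fibre contractile and 0.398 for mitochondrially encoded. If LF control 3 was left out, it was 0.247 for autophagy and lysosome, 0.111 for satellite cell, 0.116 for circadian clock and 0.15 for erythroid. If LF laparotomy 1 was left out, it was 0.112 for slow fibre contractile, 0.93 for fast fibre contractile, 0.109 for autophagy and lysosome, 0.0729 for interferon response, 0.386 for satellite cell and 0.105 for circadian clock. If LF laparotomy 2 was left out, it was 0.774 for slow fibre contractile, 0.222 for autophagy and lysosome, 0.715 for interferon response and 0.0521 for erythroid. If LF laparotomy 3 was left out, it was 0.559 for mitochondrially encoded (turned), 0.814 for extracellular matrix, 0.0565 for satellite cell, 0.0806 for circadian clock, 0.997 for erythroid (turned), 0.997 for fibroadipogenic and 0.926 for tendon. Quantile normalization ended the fast fibre call (0.915) and turned the slow fibre call (0.986). Size factors (0.114 and 0.0731) and removal of the length and GC trend (0.148 and 0.19) ended both, the last also the satellite cell call (0.133). A minimum of 5 TPM ended the satellite cell (0.121) and tendon (0.434) calls. Without the 3 Myh4 libraries the adjusted p was 0.6 for fast fibre, 0.13 for slow fibre, 0.588 for autophagy, 0.655 for interferon, 0.488 for satellite cell and 0.483 for circadian clock.

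The same question was asked of HF soleus, again with 3 libraries against 3. Higher after laparotomy were Fas, a death receptor (0.70 ± 0.14, adjusted p = 0.655), Mybpc2, the fast isoform of myosin binding protein C (3.13 ± 0.83), Sema7a (0.60 ± 0.14), Arl4d (0.42 ± 0.11) and Sap25 (0.46 ± 0.12), the last near-identical to Gm20605, which overlaps it. Lower were P3h4, a partner of collagen lysyl hydroxylase (-0.75 ± 0.17, adjusted p = 0.609), Snurf (-1.23 ± 0.27), which has the near-identical copy Gm38393, Id2 (-0.68 ± 0.16), an inhibitor of helix-loop-helix factors, Fubp3 (-0.40 ± 0.12) and Hbegf (-0.38 ± 0.11), and none of the 10 passed. Mybpc2 and Myh4, the fastest myosin, were both highest in HF laparotomy 2 (57.4 and 90.8 TPM). Limma called 0 genes (665 at an unadjusted p under 0.05, 28 higher and 637 lower), robust eBayes 0 and array weights 0. The all-gene median was -0.12 as deposited and -0.0016 with size factors. A fit on the 6 HF libraries alone called 3: Chad, a cartilage and tendon matrix protein (log2 difference -1.15, adjusted p = 0.009), Gm10217 and Gm17428. Without HF laparotomy 1 the count was 1 (Map3k6, adjusted p = 0.0173). Simulated changes of 0.5 log2 were recovered at 40.9% and changes of 1 log2 at 90.1% for this comparison. Control and laparotomy libraries did not overlap for 17.2% of genes, where chance gives 10%.

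Interferon response genes stood above other genes by camera (median 0.44 over 27, camera adjusted p = 4.89e-20, 0.535 with an estimated correlation), with Rsad2 (0.62 ± 0.27), Gbp2 (0.83 ± 0.41) and Tap1 (0.79 ± 0.39) in front. Acute phase and innate inflammation genes (0.25, camera adjusted p = 1.18e-05, 0.535 with an estimated correlation) were higher, with C3 (0.75 ± 0.34), a complement component, S100a9 (0.85 ± 0.49) and Nfkbia (0.29 ± 0.13) first. So were glucocorticoid response genes (0.19, camera adjusted p = 1.18e-05, 0.535 with an estimated correlation), with Tsc22d3 (0.35 ± 0.11), Ddit4 (0.51 ± 0.18) and Sesn1 (0.39 ± 0.15) first. Mitochondrially encoded genes stood 0.21 higher (camera adjusted p = 8.63e-06, 0.596 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.633, range 7.16e-07 to 0.633). They were led by mt-Co1 (0.28 ± 0.093), mt-Cytb (0.25 ± 0.11) and mt-Nd4l (0.29 ± 0.16), of which mt-Co1 and mt-Nd4l have near-identical nuclear copies. These 4 of 12 lists held without each library. Leaving out HF laparotomy 3 gave medians of 0.205 (interferon), 0.164 (acute phase) and 0.124 (glucocorticoid), and leaving out HF laparotomy 2 gave 0.107 (acute phase). The interferon median was 0.663 without HF laparotomy 1, and that of glucocorticoid genes 0.0595 without HF control 1, 0.292 without HF control 3 and 0.29 without HF laparotomy 1. With an estimated correlation the other 8 had adjusted p = 0.535 (Schwann and nerve), 0.596 (fast fibre) or 0.978. Upward were Schwann and nerve (median 0.37, adjusted p = 2.95e-08, first member Cnp at 0.37 ± 0.18), fast fibre contractile (0.11, 5.92e-05, first member Mybpc2 at 3.13 ± 0.83), unfolded protein (0.13, 0.00104, first member Xbp1 at 0.32 ± 0.13) and macrophage (0.16, 0.00122, first member Mrc1 at 0.29 ± 0.23). So were ribosomal (0.071, 0.0115, first member Rps28 at 0.21 ± 0.096) and erythroid (0.13, 0.0496). Tendon (-0.24, 0.00801) and fatty acid genes (-0.12, 0.0115, first member Acsl1 at -0.23 ± 0.12) were lower. Tendon members were Chad (-1.15 ± 0.29), Scx (-0.61 ± 0.20) and Angptl7 (-0.83 ± 0.28), with 4 lower over the list alone and 0 over all genes. For erythroid the adjusted p was 0.0537 omitting LF control 1 and 0.0524 omitting LF laparotomy 2. Omitting HF control 1 gave 0.101 for fast fibre. Omitting HF control 2 gave 0.0698 for fast fibre, 0.5 for erythroid (turned) and 0.365 for ribosomal. Omitting HF control 3 gave 0.667 for fatty acid, 0.0619 for macrophage and 0.0918 for tendon. Omitting HF laparotomy 1 gave 0.209 for ribosomal. Omitting HF laparotomy 2 gave 0.195 for fast fibre contractile and 0.189 for ribosomal. Omitting HF laparotomy 3 gave 0.392 for fatty acid, 0.9 for macrophage (turned), 0.764 for erythroid, 0.632 for Schwann and nerve (turned) and 0.579 for unfolded protein. Quantile normalization (0.585 and 0.28), a fast muscle covariate (0.827 and 0.535) and leaving out the 3 Myh4 libraries (0.12 and 0.107) ended the fast fibre and ribosomal calls, the last also the fatty acid call (0.0726). Of 7 settings the macrophage call held in 4 and the erythroid call in 1 (adjusted p up to 0.568 and 0.618), and a minimum of 5 TPM ended the tendon call (0.925). Before centring, the fast fibre (-0.0068) and ribosomal (-0.050) medians and the macrophage (-0.013) and unfolded protein (-0.015) means were below 0, against the upward calls.

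Averaged over LF and HF, 6 libraries on each side, 13 gene lists stood apart from other genes by camera, but 0 by fry, with an estimated correlation or by permutation of list means. Interferon response genes were higher by camera (median 0.39, camera adjusted p = 2.9e-20, 0.761 with an estimated correlation), with Psmb9 (0.54 ± 0.19), an immunoproteasome subunit, Stat2 (0.39 ± 0.16) and Tap1 (0.62 ± 0.28) first. Ribosomal protein genes (0.15, camera adjusted p = 1.2e-34, 0.369 with an estimated correlation) were led by Rps28 (0.28 ± 0.068), Rps21 (0.28 ± 0.075) and Rpl36a (0.26 ± 0.068). Heat shock proteins (0.081, camera adjusted p = 0.000981, 0.983 with an estimated correlation) were led by Hspb1 (0.35 ± 0.10), Hspa1a (0.47 ± 0.15) and Hspa1b (0.35 ± 0.14). Glucocorticoid genes (0.11, camera adjusted p = 0.00225, 0.904 with an estimated correlation) were led by Nfkbia (0.27 ± 0.089), Tsc22d3 (0.19 ± 0.075) and Ddit4 (0.26 ± 0.13). Fast fibre genes (0.13, camera adjusted p = 1.22e-05, 0.904 with an estimated correlation), led by Mybpc2 (1.45 ± 0.59), completed the 5 of 13 lists that held without each library. The interferon median was 0.211 without LF laparotomy 2, and that of glucocorticoid genes 0.0536 without LF laparotomy 3, 0.0509 without HF control 1 and 0.172 without HF laparotomy 1. That of heat shock genes was 0.0347 without LF control 1, 0.0325 without LF laparotomy 2, 0.0419 without HF control 2 and 0.0493 without HF control 3. The fast fibre median lay between 0.0503 (without HF control 1) and 0.231 (without HF control 3), and was 0.0739, 0.0735, 0.0721 and 0.201 without LF laparotomy 1, HF control 2, HF laparotomy 2 and HF laparotomy 3. The fast fibre call ended with quantile normalization (adjusted p = 0.433, range 6.62e-06 to 0.433), a fast muscle covariate (0.101) and without the 3 Myh4 libraries (0.123). The rest had, with an estimated correlation, adjusted p = 0.904 (Schwann and nerve, acute phase, tendon) or 0.983. Upward were oxidative phosphorylation (median 0.10, adjusted p = 5.56e-06, first member Ndufa1 at 0.23 ± 0.089), Schwann and nerve (0.22, 3.08e-05, first member Cnp at 0.25 ± 0.13) and acute phase (0.068, 0.0051, first member Nfkbia at 0.27 ± 0.089). So were endothelial (0.059, 0.044, first member Ly6c1 at 0.17 ± 0.11) and unfolded protein (0.04, 0.044, first member Pdia6 at 0.21 ± 0.10). Downward were tendon (-0.33, 0.000835), extracellular matrix (-0.14, 0.0163, first member Col15a1 at -0.21 ± 0.099) and circadian clock (-0.10, 0.0345, first member Tef at -0.17 ± 0.079). The adjusted p was, without LF control 1, 0.956 for extracellular matrix (turned) and 0.115 for unfolded protein. It was, without LF control 2, 0.229 for endothelial. It was, without LF control 3, 0.123 for circadian clock, 0.155 for endothelial and 0.0517 for unfolded protein. It was, without LF laparotomy 1, 0.114 for circadian clock, 0.607 for endothelial (turned) and 0.1 for unfolded protein. It was, without LF laparotomy 3, 0.836 for extracellular matrix (turned), 0.0939 for circadian clock and 0.204 for tendon. It was, without HF control 1, 0.0819 for unfolded protein. It was, without HF control 2, 0.0553 for extracellular matrix, 0.0553 for circadian clock, 0.695 for endothelial (turned) and 0.0553 for unfolded protein. It was, without HF laparotomy 1, 0.38 for oxidative phosphorylation and 0.175 for extracellular matrix. It was, without HF laparotomy 2, 0.0543 for extracellular matrix, 0.0509 for circadian clock and 0.456 for endothelial. It was, without HF laparotomy 3, 0.093 for acute phase, 0.105 for circadian clock, 0.108 for endothelial, 0.66 for Schwann and nerve and 0.679 for unfolded protein. Oxidative phosphorylation turned with quantile normalization (adjusted p = 0.773). The endothelial call turned without the 3 Myh4 libraries (median -0.071, adjusted p = 0.0719). Of 7 settings the calls held in 1 (endothelial, adjusted p up to 0.862), 2 of 6 (acute phase, 0.205), 3 (unfolded protein, 0.103), 5 (circadian clock, 0.409) and 6 (tendon, 0.51). The acute phase (-0.0063), endothelial (-0.016) and unfolded protein (-0.034) medians before centring were below 0, against their upward calls. Tendon markers showed 5 lower over the list alone and 0 over all genes, with Chad (-0.86 ± 0.21), Angptl7 (-0.64 ± 0.20) and Comp (-0.63 ± 0.23) in front, and 1 senescence gene was lower adjusted over that list alone.

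Limma called 0 single genes for the averaged laparotomy difference (747 at an unadjusted p under 0.05, 61 higher and 686 lower), robust eBayes 0 and array weights 2 (Gm10217 and Gm17428, adjusted p = 0.0117 each). Without LF control 3 the count was 2 (Chad, adjusted p = 0.0162, and Gm10171, adjusted p = 0.0159), and without LF laparotomy 1 it was 1 (Gm10217, adjusted p = 0.0187). Only 2 higher genes separated laparotomy from control in both LF and HF among named symbols, Psmc3ip (0.36 ± 0.092) and Rfc5 (0.21 ± 0.069). The first lower ones were Tbc1d1 (-0.38 ± 0.10), a regulator of glucose uptake, Rwdd3 (-0.29 ± 0.081), Masp1 (-0.37 ± 0.098), Morc3 (-0.81 ± 0.21) and Mpp5 (-0.32 ± 0.097), none of which passed. Simulated changes of 0.5 log2 were recovered at 71.6%. Genes chosen in advance for surgery and atrophy did not pass either: Fbxo32 (-0.25 ± 0.11), Trim63 (-0.031 ± 0.14), Fkbp5 (-0.019 ± 0.15), Ppargc1a (-0.10 ± 0.13), Igf1 (-0.16 ± 0.098), Cdkn1a (0.26 ± 0.37), Mt2 (0.24 ± 0.28) and Pdk4 (0.054 ± 0.22). The myosins stood at Myh7 (-0.061 ± 0.11), Myh2 (0.17 ± 0.12), Myh1 (0.065 ± 0.24) and Myh4 (0.88 ± 0.79). In LF, Fbxo32 stood at -0.36 ± 0.16 and in HF at -0.13 ± 0.16, and Trim63 at -0.11 ± 0.20 and 0.054 ± 0.20. Myostatin (Mstn) and Lcn2 were below the filter, with means of 0.5 ± 0.128, 0.397 ± 0.126, 0.227 ± 0.102 and 0.260 ± 0.155 TPM for Mstn in LF control, LF laparotomy, HF control and HF laparotomy (SD, n = 3). For Lcn2 they were 0.616 ± 0.238, 0.646 ± 0.191, 0.860 ± 0.240 and 1.11 ± 0.602 TPM. The slow myosin share differed by -3.87 points after laparotomy (exact permutation p = 0.315, smallest possible 0.005). It was -7.02 (exact p = 0.055) without HF control 3, and -2.12, -2.46 and -2.42 without HF control 1, HF control 2 and HF laparotomy 2. The mitochondrially encoded share differed by -4.28 points in LF (exact p = 0.4) and 1.4 in HF (exact p = 0.2), averaging -1.44 (exact p = 0.5). The average was -0.265, -2.54 and -0.355 without LF control 2, LF control 3 and LF laparotomy 3, -0.763 without the 10 most abundant other genes, and turned to 0.336 (exact p = 0.9) with the chromosome 1 copies of these genes counted in.

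Whether laparotomy acts differently in HF and LF was tested by the interaction, the HF effect minus the LF effect. The 5 genes with the smallest p did not pass: Arhgap29 (-0.82 ± 0.17, adjusted p = 0.685), P3h4 (-1.08 ± 0.24), Foxs1 (-0.62 ± 0.17), Nrarp (-0.54 ± 0.15), an inhibitor of Notch signalling, and Proser3 (1.10 ± 0.25). Limma called 0 genes (331 at an unadjusted p under 0.05), robust eBayes 0 and array weights 1 (Arhgap29, adjusted p = 0.0442), and without LF control 3 the count was 1 (Gm10171, adjusted p = 0.0159). Of 13 lists past camera, 3 held without each library. Mitochondrially encoded genes were higher in HF relative to LF (0.34, camera adjusted p = 2.96e-10, 0.595 with an estimated correlation), with mt-Atp8 (0.63 ± 0.32), mt-Atp6 (0.37 ± 0.17, copy Gm10925) and mt-Nd2 (0.41 ± 0.20). Ribosomal proteins were lower (-0.19, camera adjusted p = 1.53e-20, 0.595 with an estimated correlation), with Rpl15 (-0.36 ± 0.13), Rps10 (-0.45 ± 0.16) and Rpl35 (-0.38 ± 0.15). Glucocorticoid response genes were higher (0.22, camera adjusted p = 0.00376, 0.858 with an estimated correlation), with Per1 (0.51 ± 0.25), Sesn1 (0.43 ± 0.21) and Ddit4 (0.50 ± 0.26). Across 10757 genes, which are not independent replicates, the LF and HF laparotomy differences had a Pearson r of 0.0903 (exact permutation p = 0.46, smallest possible 0.01) and the same sign for 60.3%. The r turned to -0.052 without LF laparotomy 1.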

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

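The fit without the 3 libraries with Myh4 above 30 TPM and the removal of the length and GC trend were chosen after the results were seen, and the other tests in this part were planned. In 13 gene lists the laparotomy difference in HF and that in LF differed by the interaction test (camera with a preset correlation). Under an estimated correlation 0 of 34 lists passed, with adjusted p = 0.595 for the mitochondrially encoded and ribosomal lists and 0.858 for the other 11, and fry passed 0. No test of outlying samples was run within the groups of 3, and the weights of single libraries by limma ran from 0.32 in LF laparotomy 3 to 4.08 in LF laparotomy 2. For each list the interaction median, its adjusted p and the LF and HF medians are given, all relative to other genes. Higher in HF relative to LF were glucocorticoid response (0.22, 0.00376, LF 0.022, HF 0.19), acute phase (0.19, 0.00277, LF -0.038, HF 0.25), interferon response (0.11, 0.00506, LF 0.31, HF 0.44), mitochondrially encoded (0.34, 2.96e-10, LF -0.14, HF 0.21) and extracellular matrix (0.17, 0.000342, LF -0.26, HF -0.069). Higher too were macrophage (0.21, 0.00506, LF -0.087, HF 0.16), erythroid (0.73, 0.000607, LF -0.48, HF 0.13), Schwann and nerve (0.30, 0.00109, LF 0.038, HF 0.37), fibroadipogenic (0.18, 0.000638, LF -0.20, HF -0.018) and unfolded protein (0.063, 0.018, LF 0.019, HF 0.13). Lower in HF relative to LF were oxidative phosphorylation (-0.043, 0.0143, LF 0.12, HF 0.041), fatty acid (-0.19, 0.00167, LF 0.081, HF -0.12) and ribosomal (-0.19, 1.53e-20, LF 0.25, HF 0.071).

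The mitochondrially encoded, ribosomal and glucocorticoid calls held without each library, the last not without the 3 libraries with Myh4 above 30 TPM (adjusted p = 0.167). Their medians were 0.156 without LF laparotomy 3 (mitochondrially encoded), -0.124 without LF laparotomy 1 (ribosomal), and 0.0989 without HF control 1 and 0.127 without HF laparotomy 3 (glucocorticoid). The other 10 ended as follows. Minus LF control 1, adjusted p was 0.348 for interferon response, 0.0571 for oxidative phosphorylation, 0.453 for extracellular matrix (turned), 0.855 for macrophage and 0.453 for fibroadipogenic. Minus LF control 2, adjusted p was 0.176 for oxidative phosphorylation. Minus LF control 3, adjusted p was 0.0553 for unfolded protein. Minus LF laparotomy 1, adjusted p was 0.23 for oxidative phosphorylation. Minus LF laparotomy 2, adjusted p was 0.0794 for unfolded protein. Minus LF laparotomy 3, adjusted p was 0.142 for acute phase, 0.142 for interferon response (turned), 0.12 for oxidative phosphorylation, 0.309 for fatty acid, 0.415 for extracellular matrix, 0.598 for macrophage, 0.159 for erythroid, 0.142 for Schwann and nerve, 0.309 for fibroadipogenic and 0.0639 for unfolded protein. Minus HF control 1, adjusted p was 0.211 for interferon response and 0.0589 for unfolded protein. Minus HF control 2, adjusted p was 0.179 for erythroid. Minus HF control 3, adjusted p was 0.713 for oxidative phosphorylation (turned) and 0.111 for fatty acid. Minus HF laparotomy 3, adjusted p was 0.963 for interferon response, 0.125 for oxidative phosphorylation (turned), 0.0721 for fatty acid, 0.125 for extracellular matrix, 0.726 for macrophage, 0.125 for Schwann and nerve (turned), 0.154 for fibroadipogenic and 0.726 for unfolded protein. Median-of-ratios size factors ended the interferon (adjusted p = 0.188), macrophage (0.202) and oxidative phosphorylation (0.341) calls, as did quantile normalization (0.193, 0.207 and 0.765) and removal of the length and GC trend (0.192, 0.178 and 0.192). A minimum of 5 TPM ended the oxidative phosphorylation call (0.0664).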

How the results depend on the processing

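The length and GC correction, the fit without the 3 libraries with Myh4 above 30 TPM, the permutation of list means and the shares with chromosome 1 copies were chosen after the results were seen, and all other alternatives were planned. No paired analysis was possible because the labels give no numbers that link libraries of different groups. Over all alternatives, 257 values of counts stayed within 1.5 times the main count and 71 did not. For named genes 9290 values kept their side of the threshold and direction, 201 lost and 156 gained a call, and 44 moved, while 146 sign changes were of values past no threshold in either fit. For gene lists 1505 held, 478 lost their call and 30 turned. For shares and the correlation 117 held, 7 weakened, 1 strengthened and 5 turned. The cause was not tested except where the setting itself changes the genes or libraries used. Depth is unknown, so what it limits could not be measured.

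Without a filter on low values the counts were 5 in LF and 1 in HF laparotomy, 2 averaged and 2 in the interaction, 121 for HF against LF in controls and 1487 after laparotomy, since more genes at low TPM were tested (LF: Apol7e, Gm13777, Gm10662, ENSMUSG00000095720 and Gm5891, HF: Rpl13a-ps1, averaged and interaction: Apol7e and ENSMUSG00000095720). Array weights gave 2 (LF), 2 (averaged), 1 (interaction), 3127 (controls) and 6036 (after laparotomy). Fitting only the groups compared, which leaves 4 residual degrees of freedom, gave 1 in LF (Gm11874), 3 in HF and 1362 after laparotomy. Without the 3 libraries with Myh4 above 30 TPM the counts were 1 in LF (Gm10171) and 163 in controls. In controls size factors gave 1934, quantile normalization 2082, rescaled TPM 2151 and a threshold of 0.10 gave 2452. After laparotomy rescaled TPM gave 1799. Of the 4447 genes of averaged HF against LF, 3884 kept call and direction on rescaled TPM and 3001 with quantile normalization. With size factors 2860 did, and 2770 with the length and GC trend removed. Leaving out single libraries moved the counts over 0 to 1 (LF), 0 to 1 (HF), 0 to 2 (averaged), 0 to 1 (interaction), 2 to 2080 (controls) and 1048 to 4157 (after laparotomy).

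Of lists past the threshold, an estimated correlation left 0 in all 7 contrasts. Fry left 0 in LF, HF, averaged, the interaction and HF against LF after laparotomy, 1 in controls and 3 averaged over treatments. A mean of at least 5 TPM left 8 for averaged laparotomy, and 6, 11 and 8 for HF against LF in controls, after laparotomy and averaged. Size factors left 9 and 9 in the last 2, quantile normalization 9 and 9, and the length and GC correction 8 in the last. Permutation of list means left 0 for averaged laparotomy and 5 for averaged HF against LF. Single libraries moved the numbers over 9 to 14 (LF), 6 to 17 (interaction), 8 to 18 (HF against LF after laparotomy) and 10 to 17 (averaged). The lowest numbers were 9 without LF laparotomy 1 in LF, 6 without LF laparotomy 3 and 8 without HF laparotomy 3 in the interaction, 10 and 8 without these in HF against LF after laparotomy, and 10 and 10 averaged. These gene list tests turned with fry, where the value is the unchanged median: HF erythroid (0.13), ribosomal (0.071) and unfolded protein (0.13), averaged endothelial (0.059) and unfolded protein (0.04), interaction unfolded protein (0.063), glucocorticoid after laparotomy (0.11) and averaged HF against LF extracellular matrix (0.075). Quantile normalization turned LF slow fibre (0.022) and averaged oxidative phosphorylation (-0.0077). Averaged endothelial turned without the Myh4 libraries (-0.071) and, in permutation of list means, with a mean of -0.023, as did averaged unfolded protein (-0.026) and extracellular matrix in HF against LF (-0.040).

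Lists that turned without a single library ranged, in LF, over -0.29 to 0.041 (mitochondrially encoded), -0.44 to 0.026 (extracellular matrix), -0.98 to -0.24 (erythroid) and -0.70 to 0.061 (tendon). In HF they ranged over -0.25 to 0.43 (macrophage), -0.34 to 0.48 (erythroid) and -0.016 to 0.60 (Schwann and nerve). Averaged, extracellular matrix ranged over -0.24 to -0.016 and endothelial over -0.030 to 0.12. In the interaction the ranges were -0.16 to 0.41 (interferon), -0.14 to 0.062 (oxidative phosphorylation), -0.077 to 0.38 (extracellular matrix) and -0.11 to 0.54 (Schwann and nerve). A turn here is of the test, which a median need not follow. The correlation of LF and HF laparotomy differences ranged over -0.0522 to 0.191, the slow myosin share in HF minus LF over 8.92 to 13.8 points, and the mitochondrially encoded share in HF minus LF over -3 to 1.54 points in controls and 0.939 to 3.21 averaged. That averaged share (2.04 points, exact permutation p = 0.335) passed only without LF control 2 (3.21 points, exact p = 0.045). With chromosome 1 copies this share turned to 0.336 for averaged laparotomy and to 0.0341 for HF minus LF in controls.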

Other observations

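The tests of scaling, length and GC trend, batch labels, near-identical copies and chance from correlated genes were chosen after the results were seen, and those of immune cells and of other splits were written before. Of the 34 tested lists, 9 passed camera in no contrast: atrophy, proteasome, antioxidant response, insulin and IGF signalling, denervation, neuromuscular junction, cell cycle, senescence and hypoxia. In averaged HF against LF, where 649 of all 10757 genes rose and 3798 fell, members were called all the same. Among 20 atrophy genes 1 rose and 11 fell (3 and 6 with size factors, median -0.15, adjusted p = 0.501). Of 23 insulin and IGF genes, 3 rose and 12 fell (median -0.16, adjusted p = 0.569). Of 31 proteasome genes, 1 rose and 10 fell, which turned to 10 and 3 with size factors (median -0.0024, adjusted p = 0.907). The antioxidant (median 0.017, adjusted p = 0.729), denervation (0.018, 0.729), neuromuscular junction (-0.13, 0.823), cell cycle (0.0095, 0.912), senescence (0.094, 0.126) and hypoxia (0.024, 0.823) lists did not pass either.

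One library stood apart in a list tied to nerve supply, a feature singled out after its values were seen. The denervation list mean of log2(TPM + 1) was 4.66 in HF control 2 and between 3.07 and 3.64 in the other libraries. Its senescence list mean was 3.59, against 3.00 to 3.32 elsewhere. No test was run on this single library.

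HF and LF differed in 4447 of 10757 genes, 14.6% of them higher in HF. Scaling by a few abundant genes is argued against as the whole cause of these calls. On TPM rescaled without those genes 3884 kept call and direction. A length and GC trend is argued against likewise (2770 kept both without it), but the others did not, so a part stays open. What sets the excess of lower calls stays open, scaling included: 25% were higher on rescaled TPM, and size factors nearly ended it. Of 100 library splits, 1, the real one, gave as many (highest other 2408), arguing against a chance split. Because 0 label fields name a batch, date or run, a batch that follows function and function itself cannot be told apart, and a biological difference remains untested.

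All 11 genes with a fitted change of at least 4-fold before centring were pseudogenes lower in HF, 2 of them (Gm10359 and Gm12671) with identical values in every library. A change of the near-identical copy itself is argued against for the 7 whose copy was tested, since the median of these copies was -0.0259 relative to all genes. Reads moved to the copy in HF stay open: the summed TPM of these 7 and their copies had a median log2 difference of -0.116 relative to all genes (SE up to 0.121), too near the -0.152 expected with no reads moved to decide. Of 174 pseudogenes with a copy, these 11 included, 16.1% differed by at least 2-fold from all genes, against 1.53% of 196 other genes with a copy. Libraries made or quantified differently, or a genotype carried by LF mice, remain open and were not tested.

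Interferon genes stood higher after laparotomy by camera with a preset correlation. By exact permutation of list means per library, p was 0.24, so chance from correlated genes may account for it. More immune cells remain open: before centring the macrophage list mean differed by -0.0515 and the interferon list mean by 0.293, a gap of -0.345 (exact permutation p = 0.11).

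For the laparotomy counts, the 10 splits of LF and the 10 of HF are too few for a share under 0.05 (real 0 and highest other 3, real 0 and highest other 1). In the averaged contrast (real 0, highest other 4) and the interaction (real 0, highest other 2) all 100 splits gave as many, as any split must beside a count of 0, so they say nothing about chance. For HF against LF within a treatment the 10 splits are likewise too few, with 1 as large in each (real 1127 and highest other 0 in controls, real 2796 and highest other 1 after laparotomy).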
